A study of Homo sapiens with 16 samples.

How the data were processed

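Gene expression was measured by bulk RNA sequencing in alpha and beta cells of human pancreatic islets. Alpha cells make glucagon and beta cells make insulin. Per the labels' protocols, islets from cadaveric pancreas were dispersed, transduced with lentiviruses carrying short hairpin RNAs against RFX6 or a non-targeting hairpin, and kept in culture for 5 days. Per the series' design text, GFP-positive cells of each type were purified by fluorescence-activated cell sorting, and each knockdown is set against the control hairpin in cells of the same donor. The labels give 4 donors, each with a control and a knockdown library of alpha cells and of beta cells, which makes 16 libraries in 4 groups of 4. Libraries were made from polyadenylated RNA with a SMART-seq kit for low input and the Nextera XT kit and read in pairs of 150 bp, per the labels' protocols. These kits do not mark the strand, so reads of genes that overlap on opposite strands cannot be told apart.

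Trim Galore 0.5.0, STAR 2.6.1d, RSEM 1.3.1 and DESeq2 without a version are named, with the GRCh38 (hg38) genome, in the submitters' processing notes, which give neither the role nor the order of the tools. The annotation release is not given in the sources used here. The authors deposited estimated counts (expected counts, with decimals) per gene in 1 table per cell type, with 1 column per library and no normalization, as the values show. Each count table has 60664 entries, of which 5246 are named by an Ensembl identifier, 28 carry a calendar date in place of a gene symbol and hold 0.158% of the alpha and 0.156% of the beta counts, and 2 names occur more than once. The authors also deposited 1 table per cell type under the name TPM. Its values are a normalised signal and not transcript abundances, since the deposited columns sum to different totals, and each value is the truncated count divided by 1 size factor per library. All values (100%) became whole numbers on multiplication by that factor, at a tolerance of 0.01. These tables hold 19660 genes and leave out entries with 4.97% of the alpha and 8.33% of the beta counts. The alternatives that had been planned on TPM were therefore run on these size-factor values.

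The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (glmQLFit, glmQLFTest). Genes were kept by filterByExpr with a minimum count of 10, library sizes were scaled by TMM, and the donor entered as a block because the design text pairs each knockdown with its own donor's control. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05, so every adjusted p of a gene below is from this test unless another tool is named. The standard error (SE) of a log2 change is its size divided by the square root of the F statistic. Levels are TMM-scaled CPM, computed here from the deposited counts, and changes per donor used log2(CPM + 0.5). Alpha and beta cells were fitted separately. All 16 libraries entered 1 fit, with a term per donor and cell type, to test whether the change differed between alpha and beta cells. The 8 control libraries gave the comparison of alpha with beta cells. Shared calls were counted over the genes tested in both cell types, with the one-sided Fisher's exact test.

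A set of 27 gene lists with 614 entries covered islet cell identity, hormone secretion and its signalling, stress and immune responses, metabolism, and markers of the other cells a sort could carry. Each list was set against the other genes with limma 3.58.1 camera at a preset inter-gene correlation of 0.01, on log2 CPM and adjusted over the lists. At the preset, exchanging the arm labels within donors (described at the end) passed up to 9 lists in alpha cells, against 6 with the real labels. In beta cells it passed up to 10, against 15. A pass at the preset is therefore weak evidence by itself. Camera with a correlation estimated per list and fry were run beside it. No list passed in alpha or beta cells with the estimated correlation. That version tests on the residual degrees of freedom (3 in alpha and in beta cells), so few lists could pass whatever their correlation. For prohormone and granule genes in alpha cells the estimate was -0.00225, below the preset, yet the camera p went from 1.16e-06 to 0.0132. Alpha cell markers between the controls, 24 of 24 called, had adjusted p = 0.319 with it. Not passing therefore does not by itself show that correlation between genes undoes a list. Some other lists had estimates far above the preset, such as the interferon response (0.145 in alpha and 0.28 in beta cells). In beta cells acinar markers had 0.612 and nuclear-encoded oxidative phosphorylation 0.705, and in alpha cells stellate markers had 0.717. For such lists the preset understates the correlation, so their camera p at the preset may be too small. Genes were named by rule: RFX6, the hormone genes GCG, INS, SST, PPY and IAPP, the transthyretin gene TTR, the 10 rising and 10 falling genes with the largest change among those called, changed the same way in 4 of 4 donors and with a mean of at least 5 CPM, and up to 4 called members of each list (the 2 with the smallest p where fewer than 2 were called). The tests, the donor block, the lists, the rule and all but 2 of the alternatives were chosen before the data were examined. The list test of the difference between cell types was added later.

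RFX6 was counted 486 to 16355 times per library, so counting error is small beside the spread between donors. Donors 1 and 2 had 18117274 to 31404373 counts per library and donors 3 and 4 had 34741321 to 45856718, and the column codes part the same 2 sets. Each donor gave both arms, so the donor block covers this difference. The donor numbers of the labels pair the samples: over genes, the deviations of a donor's control and knockdown libraries from their group means correlated at 0.599 to 0.830, against at most 0.308 between different donors. No pair of libraries in a group was alike within sampling noise (the lowest mean chi-square per gene was 59.96). On counts simulated from these libraries, the alpha fit recovered 30.2%, 73.4% and 81.0% of genes changed 1.5-fold, 2-fold and 4-fold among 17459 genes, with 9 false calls among 126. The beta fit recovered 8.06%, 59.4% and 74.2% among 17448 genes, with 8 false among 97. False calls were more frequent with DESeq2 1.42.0 (37 of 170 in alpha and 30 of 133 in beta) and limma-voom (35 of 158 and 15 of 106). These counts were a single draw from the means and dispersions fitted by edgeR, without correlation between genes. They therefore do not rank the tools on the real data.

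Positions are from GENCODE 29 on GRCh38, in which 35994 of the 55418 symbols of the count tables (65.0%) have a gene of that name. Of 128 named genes with a position, 42 share exon sequence with a gene on the opposite strand and 14 with a gene on the same strand. The alternatives were no donor block, other scalings (RLE, upper quartile, and without these 6 genes of hormones and transthyretin), no filter and a stricter filter, DESeq2, limma-voom, the size-factor values with pseudocounts of 1 and 0.1, 1 fit of all 16 libraries, a 1.5-fold minimum, and each donor left out in turn. The 2 chosen after seeing the data were a count test on reads recovered from the size-factor values and a fit with an acinar score (the mean log2 CPM of the acinar cell markers without SPINK1) beside the donor block. The differences of the acinar score given below use all measured acinar markers, SPINK1 included. Genes on the Y chromosome and XIST are not reported. A gene that the naming rule chose for the difference between cell types is not reported here.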

Results

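The data are counts per gene of 16 libraries from sorted islet cells of 4 donors, with 4 libraries each of alpha cells and beta cells under a control hairpin and under knockdown by hairpins against RFX6. Total counts ranged from 18117274 to 45856718 per library. The glucagon gene GCG took 9.39% ± 4.02 (SD, n = 4) of the counts in control alpha cells and 0.199% ± 0.308 in control beta cells. The insulin gene INS took 7.33% ± 1.31 (SD, n = 4) in control beta cells and 0.369% ± 0.307 in control alpha cells. Transcripts of the mitochondrial genome took 1.55 to 5.65% of the counts of alpha libraries and 3.15 to 17.85% of those of beta libraries.

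RFX6 encodes a winged-helix transcription factor needed for the development of islet endocrine cells, and lies on chromosome 6 at positions 116877212 to 116932163 of the plus strand. In alpha cells it fell from 297 ± 104 CPM under the control hairpin to 68.8 ± 40.04 CPM under the RFX6 hairpins (SD, n = 4 each), a log2 change of -2.26 (SE 0.239, adjusted p = 0.014). In beta cells the means were 168 ± 37.7 and 61.4 ± 45.4 CPM, a log2 change of -1.67 (SE 0.276) that did not pass over all genes (adjusted p = 0.239). The knockdown library had less RFX6 than the control of the same donor in 8 of 8 pairs. In beta cells donor 1 kept the most, with 128 CPM against 195 CPM in its control, and the other 3 knockdown libraries had 26.9 to 50.5 CPM. The change in alpha cells minus that in beta cells was -0.59 on the log2 scale (SE 0.426, unadjusted p = 0.194 in edgeR), so a difference between the cell types was not shown. The alpha call was lost without donor 2 (-2.08, adjusted p = 0.103), donor 3 (-2.07, 0.0756) or donor 4 (-2.30, 0.107), and without the donor block (-2.11, adjusted p = 1). The beta change passed without donor 1 (-2.03, adjusted p = 0.011), with DESeq2 (0.0231) and with limma-voom (0.0333).

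**Figure D1:**
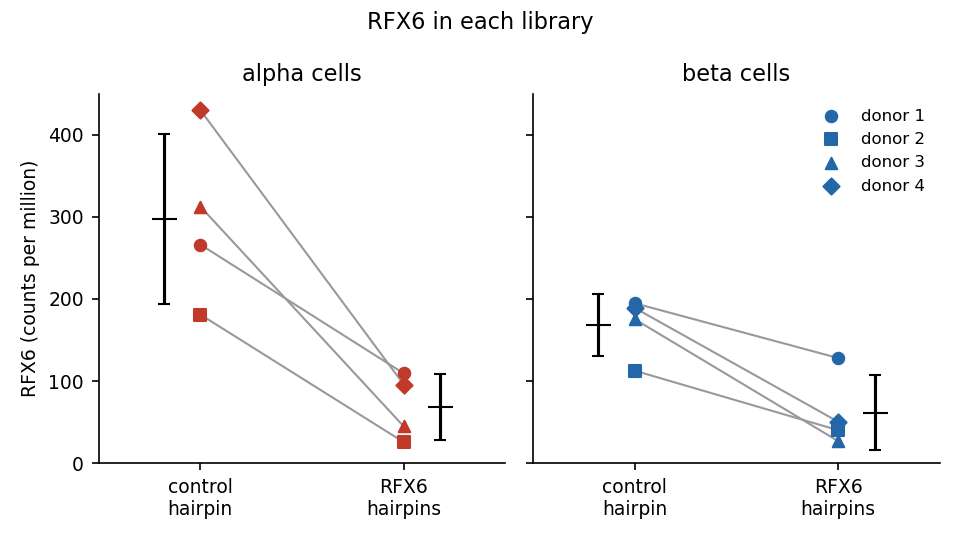
RFX6 in each library, in CPM on a linear axis, for alpha cells (left) and beta cells (right). Grey lines join the 2 libraries of a donor, and black marks give the mean and SD of the 4 libraries. All 8 lines go down, from 181 to 430 CPM to 25.6 to 109 CPM in alpha cells and from 113 to 195 CPM to 26.9 to 128 CPM in beta cells.

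The first comparison asked which transcripts change in alpha cells of adult islets when RFX6 is reduced. Among called genes with a mean of at least 5 CPM, the largest falls were in CYP4F3, a cytochrome P450 that degrades leukotriene B4 (log2 change -3.58, SE 0.511), in RFX6 itself, and in SLC5A1, the sodium-glucose cotransporter SGLT1, from 140 ± 56.8 to 33.4 ± 21.9 CPM (-2.19, SE 0.237). ALDH1A1, a retinaldehyde dehydrogenase abundant in human alpha cells, fell from 2154 ± 605 to 592 ± 263 CPM (-1.94, SE 0.302, n = 4 each). KCTD12, an auxiliary subunit of GABA-B receptors, fell from 169 ± 19.6 to 56.5 ± 18.5 CPM (-1.63, SE 0.136, adjusted p = 0.00881). TGM2, a transglutaminase, rose from 583.5 ± 235.4 to 1505 ± 755 CPM (1.34, SE 0.203, adjusted p = 0.0309), and EVA1A, which takes part in autophagy, rose by 1.099 (SE 0.0831, adjusted p = 0.00881).

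Of 18186 genes tested in alpha cells, 144 passed, 30 higher and 114 lower, each in the same direction in 4 of 4 donors. An unadjusted p under 0.05 was reached by 1980 genes, and DESeq2 and limma-voom called 743 and 415. Further falls among the largest were in KLHDC8A (-1.81), the vessel wall protein gene MMRN1 (-1.79), the calcium/calmodulin kinase gene CAMK2G (-1.77), GLT8D2 (-1.77) and PLXDC2 (-1.64). Further rises were in the serum protease gene HABP2 (1.63), the fibrinogen gene FGB (1.58), LRRN1 (1.35), C1QTNF3 (1.28), NELL2 (1.22), the phospholipase gene PLA1A (1.14), the mucin glycosylation gene GCNT3 (1.13) and PSAT1 of serine synthesis (1.01). In 1 fit of all 16 libraries HABP2 (adjusted p = 0.119), LRRN1 (0.052) and PSAT1 (0.0837) lost their calls. LRRN1 and PSAT1 also lost theirs without donor 1 (0.0654 and 0.0675). LRRN1 was not called with limma on the size-factor values (adjusted p = 0.0594 to 0.0918) or with the acinar score (0.0997). Exons of HABP2, TGM2 and LRRN1 overlap those of NRAP, RPRD1B and SUMF1 on the opposite strand, and C1QTNF3 shares exons with a read-through gene. Among genes named below, IFIT2 overlaps LIPA, PSMB8 overlaps PSMB9, FAS overlaps ACTA2, CACNA2D2 overlaps CYB561D2, CFTR overlaps CTTNBP2 and UBXN11 overlaps CD52 and SH3BGRL3 on the opposite strand. ESYT1 shares exons with ZC3H10 and INS with INS-IGF2 on the same strand. The counts of all these genes are uncertain to that extent. The genes of the hormones and of transthyretin (TTR) did not pass: GCG had a log2 change of -0.04 (SE 0.0755), INS 0.10 (SE 0.231), SST -0.05, PPY 0.61, IAPP 0.46 and TTR -0.18 (SE 0.0554, adjusted p = 0.233). Leaving out donor 1 gave 180 calls, and leaving out donor 2, 3 or 4 gave 0 in edgeR, with 1552, 1636 and 1520 genes at an unadjusted p under 0.05, 376, 426 and 368 calls by DESeq2 and 198, 184 and 133 by limma-voom. The 144 genes had a median size of 0.669, 0.691 and 0.723 in these 3 fits, against 0.726 with all donors, and 144 of 144 had an unadjusted p under 0.05, though they were selected from the same libraries. Without the donor block no gene was called (446 at an unadjusted p under 0.05, 28 by DESeq2 and 0 by limma-voom), with a median size of 0.71 for the 144. In donors 1 and 2 alone, the shallower set, edgeR called 0 genes (1257 at an unadjusted p under 0.05) with RFX6 at -2.03, and in donors 3 and 4 alone 115 genes with RFX6 at -2.48.

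**Figure D2:**
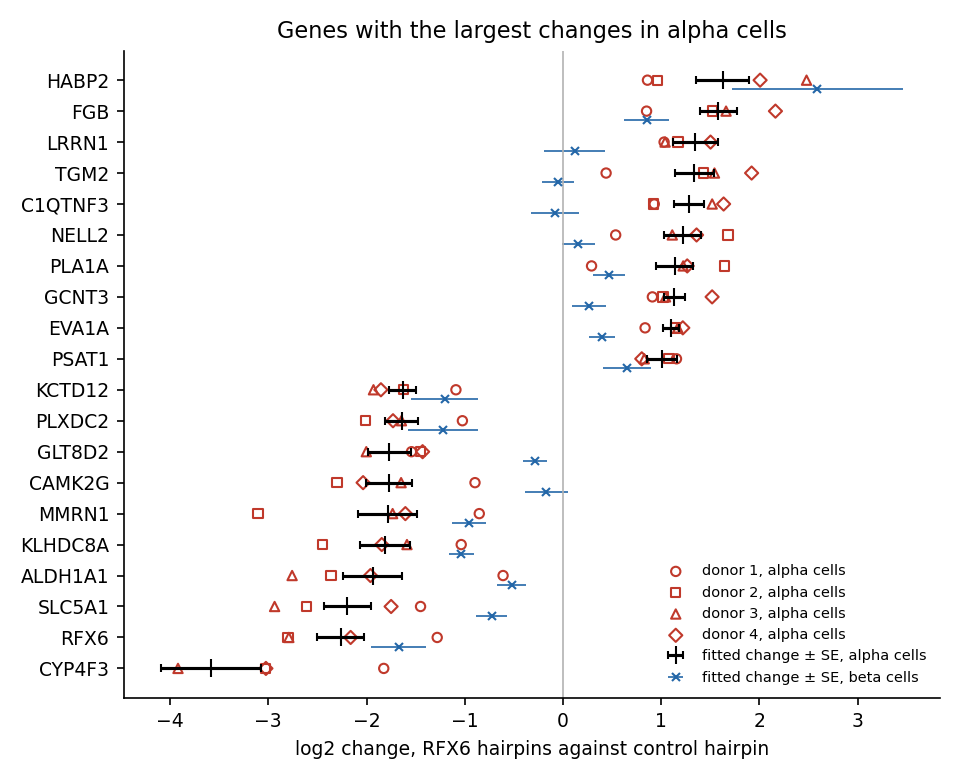
Log2 change under the RFX6 hairpins (horizontal axis) of the 10 rising and 10 falling genes with the largest changes in alpha cells. Open red symbols are the 4 donors, black bars the fitted change ± SE in alpha cells, and blue crosses the fitted change ± SE in beta cells where the gene was tested. Every donor lies on the same side of 0 for each gene, and CYP4F3 (-3.58) and HABP2 (1.63) stand at the ends.

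Some alpha cell markers and genes of granule cargo were lower. Of 24 alpha cell markers measured, KCTD12 and the phospholipase C gene PLCE1 (-1.03, SE 0.170) fell and none rose over all genes, and 10 fell and 1 rose adjusted over the list alone. Their median log2 change was -0.18 (camera adjusted p = 0.00199, but adjusted p = 0.266 with an estimated correlation). Of 19 genes of prohormone processing and granule cargo, SLC30A8, the zinc transporter of the granule, fell from 1192 ± 711 to 689 ± 388 CPM (-0.80, SE 0.110) and the calcium sensor gene SCGN by 0.70 (SE 0.104). Adjusted over the list alone 13 of the 19 fell, the median was -0.28, and the camera adjusted p was 1.05e-05 (adjusted p = 0.266 with an estimated correlation). Of 31 islet transcription factors, RFX6, ISL1 (-0.66, SE 0.0763) and the carbohydrate response factor gene MLXIPL (-0.69, SE 0.109) fell. Adjusted over the list alone 6 fell and 2 rose, and the list did not pass (camera adjusted p = 0.135).

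Single members fell in 5 further lists that did not pass as lists. RAB3B of the exocytosis machinery fell by 0.80 (SE 0.0863; of 27 genes, 17 had a positive change, and 4 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.827). The calcium channel subunit gene CACNA2D2 fell by 0.68 among 35 ion channels (6 fell and 1 rose adjusted over the list alone, 0.135). GPR119, a lipid receptor, fell from 154 ± 81.8 to 76.25 ± 25.9 CPM, a log2 change of -0.92, among 29 genes of nutrient sensing (1 fell adjusted over the list alone, 0.476). The somatostatin receptor gene SSTR2 fell by 0.51 among 29 receptors (1 adjusted over the list alone, 0.827), and RAPGEF4, the cAMP sensor EPAC2, fell by 1.11 among 34 genes of cAMP and calcium signalling (2 adjusted over the list alone, 0.451).

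Interferon-stimulated genes and p53 targets were higher. Of 28 genes of the interferon response, 5 rose: the antiviral gene MX1 (0.85, SE 0.127), the peptide transporter gene TAP1 (0.71, SE 0.0981), IFIT2 (0.57, SE 0.0692), the immunoproteasome gene PSMB8 (0.55, SE 0.0747) and ISG15 (0.76, SE 0.118). Adjusted over the list alone 12 rose, 27 of 28 had a positive change and the median was 0.46 (camera adjusted p = 1.33e-08, but adjusted p = 0.342 with an estimated correlation). Of 22 p53 targets and cell death genes, the cell cycle inhibitor gene CDKN1A rose from 483 ± 216 to 721 ± 310 CPM (0.59, SE 0.0718), and the death receptor gene FAS (0.61) and PHLDA3 (0.57) rose too. Adjusted over the list alone 13 rose and 1 fell, with a median of 0.30 (camera adjusted p = 6.82e-06, adjusted p = 0.266 with an estimated correlation). Of 22 NF-kappaB and cytokine genes, BIRC3 (0.94) and the mitochondrial superoxide dismutase gene SOD2 (0.76) rose and the chemokine gene CXCL1 (-1.01) fell, with 8 up and 5 down adjusted over the list alone (camera adjusted p = 0.451). The intermediate filament gene VIM fell by 1.25 (SE 0.217) among 15 dedifferentiation genes, of which 2 fell adjusted over the list alone (camera adjusted p = 0.272).

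Markers of other cell types moved with the hairpins in part. The 20 stellate and fibroblast markers had a median change of 0.39 with none called, over all genes or adjusted over the list alone (camera adjusted p = 0.0132, adjusted p = 0.876 with an estimated correlation), and the sign of the list test turned without donor 1 (adjusted p = 0.791). Of 7 immune cell markers CD14 fell by 0.74 and 2 fell adjusted over the list alone (camera adjusted p = 0.025, adjusted p = 0.484 with an estimated correlation). This list lost its call without donor 1, 3 or 4 (adjusted p = 0.627, 0.144 and 0.0663) and without the donor block (0.207). Of 17 acinar markers, SPINK1, a trypsin inhibitor, rose by 0.73 while the other 16 had negative changes (median -0.97, camera adjusted p = 0.177), and 18 duct markers held no call (0.177). The remaining lists had no called member and did not pass, with camera adjusted p from 0.206 to 0.868: beta cell markers, other islet cell markers, enteroendocrine genes, cilium, unfolded protein response, immediate early genes, cell cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, sterol and fatty acid synthesis, and endothelial markers.

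**Figure D3:**
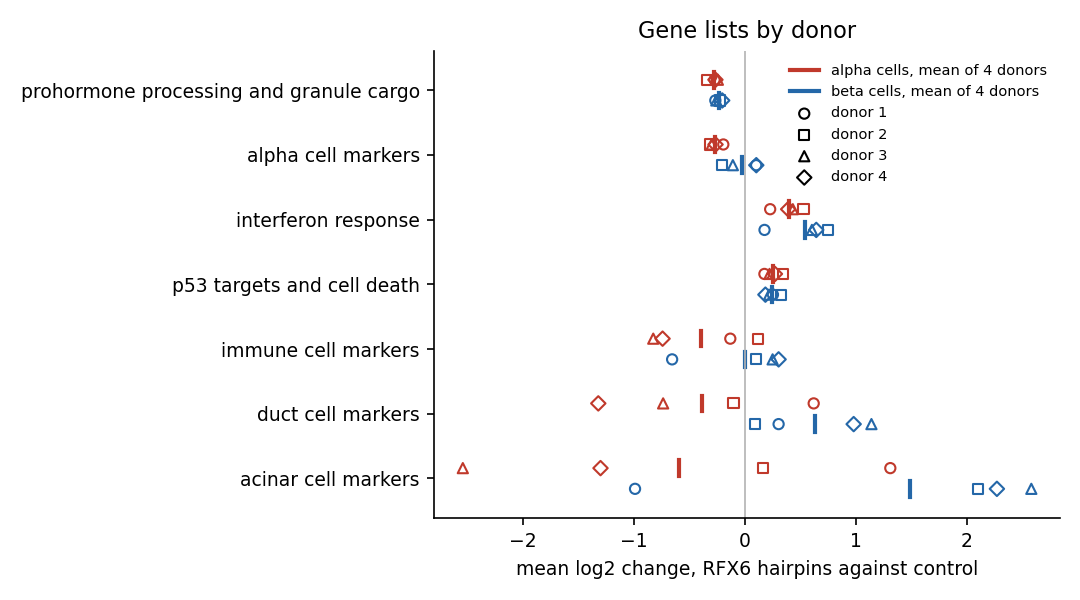
Mean log2 change of 7 gene lists in each donor (open symbols) in alpha cells (red) and beta cells (blue), with the mean of the 4 donors as a bar. Prohormone and granule genes lie below 0 in all 4 donors of both cell types (means -0.28 and -0.24) and interferon genes above 0 (means 0.39 and 0.54), while acinar markers lie on both sides of 0.

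The second comparison asked the same of beta cells, where interferon-stimulated genes were the ones to pass. IFI6 rose from 226 ± 148.5 to 641 ± 496 CPM (1.38, SE 0.141, adjusted p = 0.0399), and ISG15, a ubiquitin-like protein, rose from 47.0 ± 26.6 to 125 ± 83.7 CPM (1.31, SE 0.147, adjusted p = 0.0476), each in 4 of 4 donors (SD, n = 4). The next smallest p was that of GDF15, a stress-induced cytokine, at 0.95 (SE 0.117, adjusted p = 0.0617). VIM (-0.83, SE 0.146, adjusted p = 0.249) and ACLY, the ATP citrate lyase gene (-0.67, SE 0.134, 0.405), did not pass.

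Of 18165 genes tested in beta cells, IFI6 and ISG15 were the 2 called, 1255 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 100 and 14. The genes of the hormones and TTR did not pass, with INS at 0.16 (SE 0.141), IAPP at 0.15, GCG at 0.39 (SE 0.151, adjusted p = 0.701), SST at 0.33, PPY at 0.19 and TTR at -0.01, which turned positive under upper quartile scaling (0.022). Leaving out donor 1 gave 16 calls and leaving out donor 2 gave 7. Without donor 3 or 4 edgeR called 0 genes, with 1065 and 645 at an unadjusted p under 0.05, 53 and 23 by DESeq2 and 10 and 1 by limma-voom, and the adjusted p was 0.14 and 0.0824 for IFI6 and 0.14 and 0.301 for ISG15. Without the donor block 0 were called (121 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom). Donors 1 and 2 alone gave 23 calls with RFX6 at -1.001 (SE 0.310), and donors 3 and 4 alone 40 with RFX6 at -2.293 (SE 0.204).

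Interferon response genes were higher as a list in beta cells, with 28 of 28 positive, a median of 0.48 and 13 rising adjusted over the list alone (camera adjusted p = 6.34e-14, but adjusted p = 0.331 with an estimated correlation). The p53 targets had a median of 0.23, with 3 rising adjusted over the list alone (3.65e-05, adjusted p = 0.331 with an estimated correlation). Genes of prohormone processing and granule cargo had a median of -0.24, among them the granule membrane gene PTPRN2 (-0.51, SE 0.116, adjusted p = 0.475) and the carboxypeptidase gene CPD (-0.55, SE 0.132, 0.475), with 5 falling adjusted over the list alone (0.00036, adjusted p = 0.331 with an estimated correlation). Ion channels (median -0.19, 4 falling adjusted over the list alone, camera adjusted p = 0.000251), islet transcription factors (-0.18, 1 falling, 0.00451), nutrient sensing (-0.24, 0.00193), cAMP and calcium signalling (-0.16, 0.0114) and sterol and fatty acid synthesis (-0.18, 2 falling, 0.0363) passed downwards as well. The 1 falling islet transcription factor was RFX6, the target of the hairpins, which also entered the test of that list. Receptors had a median of -0.26 (0.0228). With an estimated correlation the adjusted p was 0.331 for these lists and 0.497 for the receptors. Nuclear-encoded oxidative phosphorylation (median 0.20, 3.65e-05) and mitochondrially encoded genes (0.24, 6.38e-05) passed upwards, with adjusted p = 0.593 and 0.386 with an estimated correlation. That correlation was 0.705 and 0.518, and no member was called over all genes or adjusted over the list alone. Fry in 1 direction gave adjusted p = 0.352 and 0.144, and in either direction 0.245 and 0.0402. Without donor 2 the receptors, cAMP and calcium signalling, nuclear-encoded oxidative phosphorylation and sterol lists lost their calls (adjusted p = 0.226, 0.253, 0.0857 and 0.240), and without donor 4 the islet transcription factors, receptors and sterol lists did (0.0618, 0.0587 and 0.0805). Without the donor block the receptors, cAMP and calcium signalling and mitochondrially encoded lists lost theirs (0.0502, 0.0507 and 0.168).

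Markers of exocrine and stromal cells were higher in the same beta libraries. The 15 acinar markers measured, which encode digestive enzymes and related secreted proteins, were all positive with a median of 2.11 and summed to 173 CPM under the control and 535 CPM under the RFX6 hairpins on average (camera adjusted p = 5.23e-08, adjusted p = 0.331 with an estimated correlation). REG1A went from 60.2 ± 66.2 to 279 ± 344 CPM (3.17, SE 0.781, adjusted p = 0.489), and 3 of the 15 rose adjusted over the list alone. Duct markers had a median of 0.56, among them the chloride channel gene CFTR (2.21, SE 0.448, adjusted p = 0.405), with 6 rising and 1 falling adjusted over the list alone (1.17e-05, adjusted p = 0.331 with an estimated correlation). Stellate markers (median 0.29, 0.0363) and endothelial markers (median 0.51 over 6 genes, 0.00429) passed too, with adjusted p = 0.636 and 0.331 with an estimated correlation, and the stellate call was lost without donor 3 or 4 (0.822 and 0.181). The remaining 12 lists did not pass in beta cells.

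Whether the change differed between alpha and beta cells was tested directly, and no single gene passed. Among the smallest p-values were those of GLT8D2, lower by 1.77 in alpha cells, with a difference of -1.46 (SE 0.225), the membrane contact site gene ESYT1 (0.74, SE 0.118), UBXN11 (1.03) and DIP2C (0.74), with adjusted p from 0.434 to 0.460. Of 20565 genes tested, edgeR called 0, with 1142 at an unadjusted p under 0.05, while DESeq2 called 53 and limma-voom 3. Without donor 1, edgeR called 5. On simulated counts this fit recovered 4.62%, 26.6% and 60.9% of differences of 1.5-fold, 2-fold and 4-fold, so most 2-fold differences would be missed.

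Genes called in alpha cells tended to move the same way in beta cells. Of 143 of them also tested in beta cells, 132 had the same sign there, and 71 had the same sign with an unadjusted p under 0.05 and 0 the opposite sign, where 7.12% of all beta genes reached that p. The falling genes had a median log2 change of -0.70 in alpha and -0.39 in beta cells, and the rising genes 0.745 and 0.30. These genes were selected by their alpha change, which alone makes their changes smaller in the other comparison, so the medians do not compare the cell types. ISG15 was the 1 gene called in both, where independent lists would share 0.0167 (one-sided Fisher's exact p = 0.0166 over 17112 genes, which are not independent replicates). The shared count was 3 without donor 1 and 0 without donor 2, 3 or 4, and 0 without the donor block. Over 11061 genes with at least 5 CPM in both, changes correlated at r = 0.21 and rho = 0.23, across genes. The 2 comparisons used different control libraries of the same donors.

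**Figure D4:**
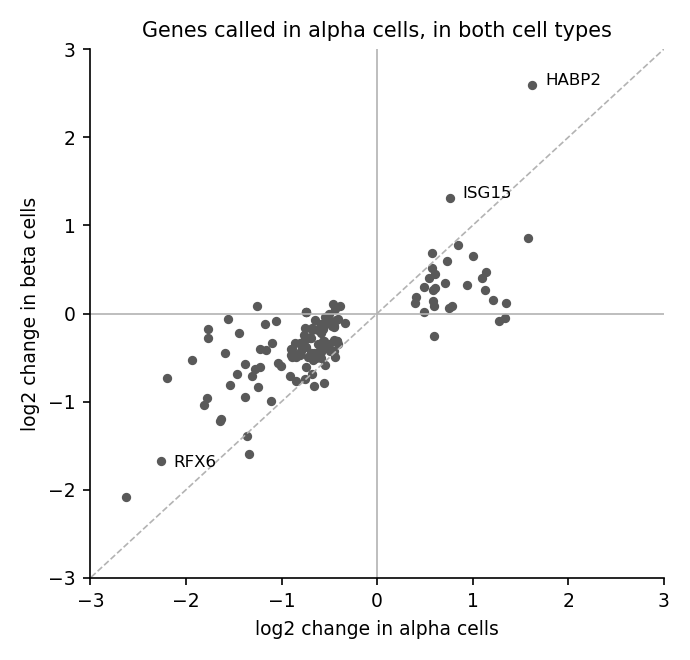
Log2 change in beta cells (vertical) against that in alpha cells (horizontal) for the 143 genes called in alpha cells and tested in both, 1 point per gene, with equal change as a dashed line. Of these, 132 lie in the quadrants of equal sign. The genes were selected by their alpha change, so their distance from the dashed line does not compare the cell types.

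Control alpha and beta cells differed in the genes that define them, and RFX6 was higher in alpha cells by 0.82 on the log2 scale (SE 0.152, adjusted p = 0.0132). GCG was higher in alpha cells by 7.17 (SE 0.999, adjusted p = 0.00472) and TTR by 4.93, and INS (-4.81, SE 1.05, adjusted p = 0.0238) and IAPP (-5.15) were lower. The homeobox gene IRX2 stood at 107 ± 14.2 CPM in alpha and 2.11 ± 1.44 CPM in beta cells, and KCTD12 at 170 ± 19.7 and 8.94 ± 5.85 CPM. The prohormone convertase gene PCSK1 (202 ± 119 against 1849 ± 734.5 CPM) and the noncoding RNA MEG3 (153 ± 139 against 1895 ± 1218 CPM) were lower in alpha cells.

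Of 18075 genes tested between the controls, 2809 passed, 1466 higher and 1343 lower in alpha cells. All 24 alpha cell markers were higher, including FXYD5 (4.33) and SMOC1 (2.72), and 25 of 26 beta cell markers were lower, including ADCYAP1 (-4.40) and ENTPD3 (-3.67), with the same counts adjusted over the list alone (camera adjusted p = 2.22e-18 and 1.71e-17, and adjusted p = 0.319 with an estimated correlation for each). RBP4 (-3.78), AQP3 (-1.77) and ACSL1 (-1.29) of the markers of other islet cells were lower in alpha cells, and the AQP3 call was lost without donor 1 (-1.55, adjusted p = 0.103). NF-kappaB and cytokine genes were higher in alpha cells, 12 of 22 over all genes and 16 adjusted over the list alone (camera adjusted p = 1.42e-06, adjusted p = 0.319 with an estimated correlation). The 13 mitochondrially encoded genes were lower, 12 over all genes and 13 adjusted over the list alone (2.61e-07, adjusted p = 0.401 with an estimated correlation). Acinar markers were higher in alpha cells, with 4 of 16 called over all genes and adjusted over the list alone, SPINK1 (3.28) among them, and a median of 3.30 (0.000195, adjusted p = 0.484 with an estimated correlation). Duct markers, with 6 higher and 1 lower over all genes, 9 and 2 adjusted over the list alone and a median of 1.63 (camera adjusted p = 0.00342), and stellate markers, 20 of 20 positive with none called over all genes or adjusted over the list alone (0.0228), were higher too, with adjusted p = 0.484 and 0.709 with an estimated correlation. Nuclear-encoded oxidative phosphorylation (camera adjusted p = 0.000257), p53 targets (0.00332), immediate early genes (0.00879), dedifferentiation genes (0.00901) and the interferon response (0.0403) passed upwards, and markers of other islet cells (0.00901) and ion channels (0.0277) downwards, with adjusted p of at least 0.319 with an estimated correlation. LCN2 is in both the NF-kappaB and the duct list, and SOX9 in both the dedifferentiation and the duct list. Whether exocrine RNA in the alpha libraries contributes to the higher NF-kappaB and dedifferentiation lists was not tested. Leaving out donor 1, 2, 3 or 4 gave 1563, 1695, 1682 and 1822 calls, the fit without the donor block 1761, and DESeq2 4622.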

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

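The tests below of immune cells, of the hairpins and their virus, of acinar RNA and its donors, of the spread in beta cells and of the RFX6 difference, and the list tests of the difference between cell types, were chosen after the result was seen, and so was the thinning without mitochondrially encoded genes. The thinning to an equal total count was planned.

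Interferon response genes were higher under the RFX6 hairpins in both cell types, with a mean log2 change over donors of 0.394 (SE 0.0626) in alpha and 0.543 (SE 0.126) in beta cells, positive in 4 of 4 donors each. By fry in 1 direction the list did not pass (adjusted p = 0.0589 in alpha and 0.126 in beta cells). Immune cells in the sort, which sorting for GFP-positive islet cells would be meant to remove, may contribute. Their markers argue against it in alpha cells, where 6 of 7 were lower, CD14 was called lower and the list passed downwards (camera adjusted p = 0.025, adjusted p = 0.484 with an estimated correlation), but the mean over donors was -0.395 (SE 0.231) in alpha and 0.000195 (SE 0.222) in beta cells, both within 2 SE of 0, so this stays open. The control cells were transduced too, with a non-targeting hairpin, so a response to any such virus or hairpin would be in both arms. All 8 knockdown libraries had less RFX6 than their controls, and the labels do not say which hairpin against RFX6 a library carried. A response particular to the RFX6 hairpins or their virus therefore cannot be told apart from a response to less RFX6. Donor 1 had the smallest fall of RFX6 and the smallest interferon rise in both cell types. That rise was 0.228 against 0.39 to 0.528 in alpha cells and 0.177 against 0.604 to 0.747 in beta cells. An effect of the hairpins themselves could follow the same order, so this does not separate them from less RFX6. A role of RFX6 itself remains among the open explanations, as a hypothesis untested beyond this design.

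Acinar markers were higher in knockdown than in control beta cells in 3 of 4 donors and in knockdown alpha cells in 2 of 4, and the paired difference of the score of all measured acinar markers averaged 2.06 in beta and -0.657 in alpha cells. The beta rise is not that of 1 donor alone, as the mean change was 2.10, 2.58 and 2.27 in donors 2, 3 and 4 against -0.989 in donor 1 and the list passed upwards with each donor left out (highest camera adjusted p 0.000394, but adjusted p = 0.331 with an estimated correlation over all donors), while the rise is uncertain wherever donor 1 is kept: 1.29 (SE 1.14), 1.13 (SE 1.06) and 1.23 (SE 1.12) without donor 2, 3 or 4, and 2.32 (SE 0.141) without donor 1. RNA of acinar cells carried into the sort in amounts that vary from library to library is a candidate explanation, although sorting for GFP-positive islet cells would be meant to remove such cells, and it stays open beside an effect of the hairpins, since the score was higher in 5 of 8 knockdown libraries and 8 pairs are too few to tell these apart. Duct markers, which that score leaves out, were higher under knockdown in 4 of 4 beta donors (0.304, 0.0906, 1.14 and 0.98), donor 1 included. In alpha cells they were higher in 1 of 4 donors (mean -0.384, SE 0.417). With the score without SPINK1 as a covariate 98 genes were called in alpha cells, of which 85 were among the 144. The 59 calls lost included those of FAS, PHLDA3, BIRC3, CXCL1, VIM, GPR119, SSTR2, CACNA2D2, MLXIPL and PLCE1. Of the largest changes NELL2 (adjusted p = 0.0677), PLA1A (0.0759), MMRN1 (0.0867) and LRRN1 (0.0997) lost theirs too. Over the 144 genes the median size went from 0.726 to 0.689 and the median SE from 0.0988 to 0.102. In beta cells 0 genes were called in that edgeR fit. IFI6 went from 1.38 (SE 0.141) to 1.28 (SE 0.220, adjusted p = 0.724) and ISG15 from 1.31 (SE 0.147) to 1.09 (SE 0.212, 0.957). RFX6 went from -1.67 (SE 0.276) to -1.03 (SE 0.276). The covariate takes 1 residual degree of freedom in both cell types. Beta donor 1, whose acinar markers alone fell, also had the smallest fall of RFX6 (from 195 to 128 CPM). The score thus partly follows the strength of the knockdown in beta cells, and that fit cannot separate acinar RNA from the hairpins.

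More genes were called in alpha cells (144) than in beta cells (2), as without donor 1 (180 and 16) and in donors 3 and 4 alone (115 and 40). The edgeR counts turned without donor 2 (0 in alpha and 7 in beta cells, with 1552 and 1221 at an unadjusted p under 0.05, 376 and 164 by DESeq2, 198 and 56 by limma-voom) and in donors 1 and 2 alone (0 and 23, with 1257 and 617 at that p), and were 0 in both without donor 3 (1636 and 1065 at that p, 426 and 53 by DESeq2, 184 and 10 by limma-voom) or donor 4 (1520 and 645, 368 and 23, 133 and 1). Total depth does not account for the order over all donors: with all 16 libraries thinned to 18117243 counts, 195 genes were called in alpha and 4 in beta cells, and with counts outside mitochondrially encoded genes thinned to 16607436, 198 and 4. A larger spread in beta cells may contribute, as the median SE over 11061 genes was 1.3 times that in alpha cells, a ratio between the bounds that would have decided it. On simulated counts the beta fit recovered fewer genes, 8.06% against 30.2% in alpha cells at 1.5-fold and 59.4% against 73.4% at 2-fold. In that draw it found fewer changes of a given size, but how much of the order this accounts for was not tested. A smaller fall of RFX6 in beta cells stays open too (unadjusted p of the difference 0.194 in edgeR). A difference in how the cell types depend on RFX6 is the biological alternative, and the test of the difference itself called 0 genes in edgeR (1142 at an unadjusted p under 0.05, 53 by DESeq2 and 3 by limma-voom). That test recovered 26.6% of simulated 2-fold differences, so its 0 calls do not decide the question.

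The change of 5 gene lists differed between alpha and beta cells by camera with the preset correlation, each lower in alpha cells: acinar markers (adjusted p = 3.02e-06), duct markers (9.4e-05), mitochondrially encoded genes (0.000183), nuclear-encoded oxidative phosphorylation (0.00868) and alpha cell markers (0.0172). Each had adjusted p = 0.668 with an estimated correlation.

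Of 204 groups of 4 values examined, 11 held 1 value set far apart from the other 3, where chance alone gives about 1 in 20, or 10.2. In alpha cells ISL1 changed by -0.4175 in donor 1 against -0.76 to -0.71 in the others, and RAPGEF4 by -1.623 in donor 3 against -0.91 to -0.87. In beta cells SYT11 had a change of -0.2747 in donor 4 against -0.32 to -0.31, and CHGA of 0.2281 in donor 2 against -0.95 to -0.77. Between the control libraries, the alpha minus beta difference of KCTD12 was 3.201 in donor 2 against 4.61 to 4.87, and that of ENTPD3 was -2.422 in donor 1 against -4.09 to -3.82. Both beta libraries of donor 2 stood apart in GCG, which took 0.6581% of counts in the control (95% Wilson interval 0.6547 to 0.6615%) against 0.0208 to 0.0910% in the other 3, and 0.911% in the knockdown (0.9068 to 0.9153%) against 0.0228 to 0.121%. These intervals cover counting error only. In CPM, GCG was 6251 against 217 to 910 in the controls and 9404 against 220 to 1192 in the knockdowns, and PPY in the control of donor 2 was 2749 CPM against 19.9 to 267.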

How the results depend on the processing

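The count test on recovered reads and the fit with the acinar score were chosen after the data were seen, and the other settings were planned. Counts of called genes stayed within 1.5 times under RLE and upper quartile scaling and without the 6 genes of hormones and transthyretin in all comparisons. Where a setting moved a count, the order below is alpha cells (144), beta cells (2) and calls shared by both (1). Without the donor block the counts were 0, 0 and 0, and the alpha to beta control comparison gave 1761 in place of 2809. With no filter on low counts they were 852, 170 and 50, and 209 genes differed between the cell types in their change in place of 0. In that fit the prior degrees of freedom became infinite, against 5.27 in alpha and 6.78 in beta cells with the filter, so the spread of single genes was no longer used. With a mean of at least 5 CPM they were 325, 9 and 6, on fewer genes (11663 and 11707 tested). DESeq2 gave 743, 100 and 46, with 53 for the difference between cell types and 4622 for the controls, and limma-voom gave 415, 14 and 9, with 3 for the difference. The size-factor values + 1 gave 255, 6 and 4, the size-factor values + 0.1 gave 4 in beta cells and 2 shared, and with + 1 and no filter 0 in beta cells and 0 shared. All 16 libraries in 1 fit called 73 genes in alpha cells, of which 65 were among the 144. The other calls of the 144 were lost, those of HABP2, LRRN1 and PSAT1 among them. In beta cells that fit called 2, ISG15 and, lower, NCAM1 (named after its value was seen), while IFI6 lost its call (1.38, adjusted p = 0.0545). Recovered reads gave 221, 5 and 3, and the acinar score gave 0 in beta cells and 0 shared. Leaving out 1 donor gave 0 to 180 in alpha cells, 0 to 16 in beta cells, 0 to 3 shared, 0 to 5 for the difference and 1563 to 1822 for the controls. With 3 donors, 2 residual degrees of freedom were left, and 4 for the difference. The RFX6 change was -2.11 in alpha cells without the donor block (no longer called) and -2.59 to -2.07 with 1 donor left out. In beta cells RFX6 was called with no filter (-1.64), with a mean of at least 5 CPM (-1.67), with DESeq2 (-1.67) and with limma-voom (-1.67), and lay between -2.03 and -1.30 with 1 donor left out. Gene lists passing went from 6 in alpha cells to 0 with an estimated correlation, 3 by fry in 1 direction and 15 by fry in either direction, and from 15 in beta cells to 0, 2 and 9. Fry in 1 direction passed prohormone and granule genes (adjusted p = 0.0181 in alpha and 0.033 in beta cells) and p53 targets (0.0397 and 0.033). It also passed alpha cell markers in alpha cells (0.0181), but not the interferon response (0.0589 in alpha and 0.126 in beta cells). Stellate markers in alpha cells turned downwards without donor 1 (camera adjusted p = 0.791, and as low as 0.000496 without donor 3). The other reversals were in genes that were not called. In alpha cells they were GCG (0.0432 and 0.00896 without donor 3 or 4, -0.137 without donor 1, 0.0426 with the acinar score), INS (-0.0175 without the donor block, -0.157 to 0.439 with 1 donor left out), SST (0.101 and 0.105 without donor 1 or 2, -0.302 without donor 4) and IAPP (-0.0265 to 1.001 with 1 donor left out). In beta cells they were INS (-0.0426 to 0.286 with 1 donor left out, -0.113 with the acinar score), PPY (-0.0596 without the donor block, -0.0998 to 0.554 with 1 donor left out, -0.483 with the acinar score), IAPP (-0.0632 to 0.280 with 1 donor left out), LYZ (-0.0756 to 0.977 with 1 donor left out) and HLA-DRA (-0.996 to 0.0634 with 1 donor left out). TTR in beta cells was 0.227 without the donor block, 0.0224 under upper quartile scaling, 0.0186 with no filter, 0.0133 with limma-voom, 0.0223, 0.121 and 0.000183 without donor 1, 3 or 4 (-0.150 without donor 2), and 0.00806 on recovered reads. For settings where no reason is given, the cause was not tested. Among fits of single named genes other than RFX6, with 1 donor left out, 83 kept and 137 lost a call and 6 gained one. In the other settings 623 kept and 81 lost a call and 105 gained one. The 1.5-fold minimum left 101 calls in alpha cells. Size-factor values were not used for the comparisons across cell types, since the tables of alpha and beta cells were normalised separately. In the simulated alpha data 30.2% of genes changed 1.5-fold were recovered, and 8.06% in beta cells, so changes of that size can be missed at 4 donors.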

Other observations

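The genes in the next sentences were chosen after their values were seen, and the splits of the samples were planned. They are 6 called genes outside the lists, and no test of a shared class was made. In alpha cells the orphan receptor gene GPR148 went from 6.93 ± 2.82 to 1.14 ± 0.702 CPM (-2.63, SE 0.387, adjusted p = 0.0297), the adenylyl cyclase gene ADCY2 from 75.0 ± 24.1 to 26.7 ± 11.2 CPM (-1.54, SE 0.220, adjusted p = 0.0269), and UCN3, which encodes the peptide urocortin 3, from 26.7 ± 15.0 to 11.2 ± 7.25 CPM (-1.28, SE 0.183, adjusted p = 0.0264), all n = 4. The potassium channel gene KCNA5 fell by 1.36 (SE 0.170, adjusted p = 0.0183), the prostaglandin E receptor gene PTGER4 by 1.16 (SE 0.201, adjusted p = 0.0468) and the neurotrophin receptor gene NTRK2 by 0.89 (SE 0.144, adjusted p = 0.0387). Each moved down in 4 of 4 donors. In beta cells none of the 6 passed: KCNA5 had a log2 change of -1.39 (SE 0.288, adjusted p = 0.429), UCN3 of -0.63 (SE 0.204) and ADCY2 of -0.81 (SE 0.295).

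The labels of the 2 arms compared (control and knockdown, or alpha and beta among the controls) were exchanged within donors in every way that parts all 4 donor pairs, which makes 8 splits with the real one, too few for a share under 0.05. In alpha cells the real split called 144 genes and the highest other 0, so 1 of 8 was as large, and 24 splits that part 2 pairs called 0. With the donor block these 24 give the same fits in pairs. Each rests on the 2 donors that it parts, so their 0 calls add little. In beta cells it was 2 against 0 (1 of 8), for calls shared by both cell types 1 against 0 (1 of 8), and for alpha against beta controls 2809 against 0 (1 of 8). For the difference between cell types, control and knockdown were kept and the alpha and beta labels of a donor's 2 paired changes were exchanged. There the real split and the others called 0, so 8 of 8 were as large. For gene lists in alpha cells the real split passed 6 and the highest other 9, with 3 of 8 as large, and in beta cells 15 against 10, with 1 of 8 as large, while splits that part 2 pairs passed up to 9 and 13. Splits that follow the donors were fitted without the block. For donors 1 and 2 against donors 3 and 4 they called 685 genes in alpha and 1135 in beta cells. The other such splits called 0 and 13 in alpha and 19 and 6 in beta cells. Each side held 2 donors, and both libraries of a donor entered as independent replicates, which inflates these counts. By themselves they therefore do not show a structure by donors or their batch.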
